A study of Rattus norvegicus with 6 samples.

How the data were processed

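Strand-specific mRNA libraries were made per the labels' protocols and cover 6 cultures of postnatal rat hippocampus, with 3 biological replicates treated for chemical long-term potentiation (cLTP) and 3 treated with DMSO. The labels call the cultures biological replicates and do not say whether they came from separate litters or days, so p-values measure the spread between these cultures. The labels' text on the RNA that entered the libraries names sorted cells of operated animals, which does not match the cultures named in the other labels, so this part of the protocol was not used. Per the submitters' processing notes, bcl2fastq, STAR and DESeq2 were used with the rat genome build rn6; their versions, the counting tool, its strand setting and the annotation release are not given in the sources used here. Reads shared by near-identical gene copies or by overlapping genes could therefore have been assigned in ways that are not known here.

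The deposited table holds 1 signal value per gene and library for 32883 gene rows, without division by gene length. In each library 100% of the values above 0 were whole multiples, within 0.01, of the value of a single read, as deposited read counts divided by 1 size factor per library would be. Whole reads were recovered by dividing each column by that value (0.878 to 1.13). The recovered totals were 11869519, 12776185 and 10988014 reads in DMSO 1, 2 and 3, and 10668973, 11792935 and 11673464 in cLTP 1, 2 and 3, and between 17864 and 18298 rows had at least 1 read. At this depth 3 reads corresponded to a normalised value of 2.63 to 3.38, so genes near that level were measured with low precision. Replicates within a group differed by more than counting noise (chi-square per degree of freedom of 4.01 to 20.0), and none was a repeat of another.

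The design planned edgeR for counts and limma for normalised values, and because the table holds normalised values, limma was the main test. The analysis used R 4.3.3 and limma 3.58.1 (eBayes with trend and robust) on log2(value + 1), for the 17315 genes with a mean value of at least 1, comparing 3 cLTP with 3 DMSO libraries without a block. P-values are two-sided and were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. A fold change on this scale understates the change of low genes. Count tests on the recovered reads were alternatives: edgeR 4.0.16 (quasi-likelihood test, TMM, filterByExpr) called 1623 genes, and DESeq2 1.42.0 called 1642.

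Both groups number their cultures 1 to 3. After removing the group means, same-numbered libraries correlated across genes with 0.22, 0.30 and 0.54, each above the limit of 0.1, and each library correlated best with its own number, so the numbers were taken to pair the libraries. DMSO 1 with cLTP 2 (0.19) and DMSO 2 with cLTP 1 (0.16) also lay above that limit, so the check sets culture 3 apart more clearly than it parts cultures 1 and 2. The pairing rests on this check, as the labels do not state it. The fit with the culture number as a block is given where it changes a call or moves a count by over 1.5 times. The fits that left out 1 library had no block and so also broke a pair. A call lost there could still hold in the block fit of all 6 libraries.

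The 30 gene lists, the test design, most of the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 largest increases and 12 largest decreases among genes past the threshold that had a mean value of at least the median of the tested genes (195), all cLTP libraries on 1 side of all DMSO libraries and an established symbol. It added Hdac1 and Hdac2 and, from each list, up to 2 higher and 2 lower members with the lowest p, and allowed others only where all members past the threshold were listed. A few list members that the rule takes are not reported here by name, but are included in all counts. The marker genes plotted by library and those of the additional observations were chosen after their values were seen. Of 559 list genes, 544 matched the table by symbol and 2 by a synonym; the other 13 were not analysed here. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 30 lists, and again with an estimated correlation and with fry. Camera called 11 lists, 0 of them with the estimated correlation (6 at an unadjusted p under 0.05). Fry, which tests whether a list's genes move on balance in 1 direction, called 8, all among these 11. The lists called by camera but not by fry were the unfolded protein and integrated stress response (fry adjusted p = 0.117), extracellular matrix (0.0665) and inhibitory neuron markers (0.137).

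The tests were checked on simulated counts with 200 changed genes per simulation, drawn for this comparison. Over 20 simulations limma recovered 45.4% of genes changed 1.5-fold, 81.8% at 2-fold and 96.4% at 4-fold, and 8.45% of its calls were false. With the block the shares were 43.4%, 80.7% and 96.8%, with 11.4% false calls. The simulated libraries were drawn independently, without a culture effect. These shares therefore do not show how the block performs where same-numbered libraries correlate. In 5 simulations edgeR gave 51.7%, 81.7% and 98.5%, with 9.51% false calls. Camera called 20 of 20 raised lists and 1 of 20 null lists at an unadjusted p of 0.05. The simulated genes were independent and the lists random, so this does not check camera on lists of correlated genes. In the data the estimated correlations were 0.48, 0.33 and 0.18 for the lists of early genes, effector genes and CREB targets.

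The alternatives changed the pseudocount, the filter on low values, the scaling, the test, the threshold, the block and the libraries included, leaving out each library in turn. The edgeR test with TMM, with and without the block, TMM scaling and equal totals of the deposited values, and the fits without culture 3 were added after seeing the data. No gene coordinates are given, as the reference gene table used for synonyms and gene spans may be of another build.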

Results

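Polyadenylated RNA was sequenced from primary hippocampal cultures of newborn Wistar rats (postnatal day 0), which hold neurons together with glial cells. On days 13 to 15 in vitro, 3 cultures received a chemical form of long-term potentiation (cLTP) and 3 control cultures received the solvent DMSO. The cLTP mixture held 50 µM forskolin, which activates adenylyl cyclase and so raises cyclic AMP, 50 nM rolipram, which inhibits cyclic AMP phosphodiesterases of the Pde4 family, and 200 µM picrotoxin, which blocks inhibitory GABA-A receptors. The time between adding the mixture and harvest is not given in the sources used here. The 6 libraries held between 10668973 and 12776185 gene-assigned reads each, and 17315 genes had a mean normalised read count of at least 1 and were tested. On the first principal component, with 38.4% of the variance, all 3 cLTP libraries lay apart from all 3 DMSO libraries. The second component, with 31.4%, set culture 3 of both groups apart from cultures 1 and 2. Values below are mean normalised read counts ± SD with n = 3 libraries per group, and folds are on the log2(value + 1) scale.

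The comparison of cLTP with DMSO asks which transcripts change when these cultures are stimulated. The series concerns the dependence of nuclear changes on the histone deacetylase Hdac1. By their labels the groups differ only in stimulation, and no library has Hdac1 altered, so this dependence was not measured here. Among genes past the threshold with a mean over all 6 libraries of at least 195, the 12 increases taken by the rule ranged from 17.7-fold to 136-fold. The cLTP values alone can lift a gene over that mean, so large folds can rest on low control values. This held for Gprc5a (5.91 in DMSO 3), Il11 and Serpinb2 (mean 24.2 in DMSO). Gprc5a, which encodes an orphan G protein-coupled receptor, rose from 25.4 ± 26.9 to 2499 ± 536 (136-fold, limma adjusted p = 0.00192). The transcription factor genes Fosb (41.8-fold), Klf4 (41.5-fold), Npas4 (39.2-fold), Nr4a2 (38.5-fold) and Nr4a1 (27.5-fold) followed. Nr4a1, an orphan nuclear receptor, reached 15577 ± 1853 from 586 ± 204. The cytokine gene Il11 rose 26.0-fold, from 24.5 ± 5.05 to 665 ± 169. Cwc25, a splicing factor gene, rose 22.6-fold, the kinase gene Sik1 rose 20.3-fold, and Serpinb2, an inhibitor of plasminogen activators, rose 20.2-fold. Adamts1, a secreted metalloprotease, rose 17.7-fold, and Thbs1, an extracellular matrix glycoprotein, rose 17.7-fold. Leaving out 1 control library moved the folds of 4 of these genes by over 1.5 times, and with them the order of the genes. Without DMSO 1 the fold was 242 for Gprc5a, 70.4 for Fosb and 64.1 for Npas4. Without DMSO 3 it was 84.1 for Gprc5a, 22.3 for Npas4 and 11.8 for Thbs1, and without culture 3 of both groups 89.7 for Gprc5a and 21.7 for Npas4.

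The largest decreases were smaller in size than the largest increases. Csf1, a growth factor for macrophages and microglia, fell from 719 ± 262 to 179 ± 36.6 (0.259-fold, limma adjusted p = 0.00355). Pdgfrb, a growth factor receptor of mural cells, fell to 0.284-fold of control, the scaffold gene Ahnak fell from 960 ± 271 to 283 ± 60.8, and Txnip, an inhibitor of thioredoxin, from 1340 ± 249 to 411 ± 88.2. The other genes in this group were Rgs16 (436 ± 131 to 169 ± 19.7), which encodes a regulator of G protein signalling, the receptor gene Notch1 (0.404-fold), the transcription factor genes Klf10 (0.404-fold) and Klf15 (0.406-fold), Als2cl (0.414-fold), Tsku (0.437-fold), Rassf4 (0.447-fold) and Zfp36l2 (0.452-fold), an RNA-binding protein that promotes mRNA decay.

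Over all genes, 1561 passed an adjusted p of 0.05 in limma, of which 988 were higher and 573 lower after cLTP, and 470 of the higher genes but 72 of the lower ones changed at least 2-fold. With the culture number as a block, 4075 genes passed (2225 higher, 1850 lower). The split between higher and lower genes depended on the scaling: 823 were higher and 1322 lower when all libraries were scaled to equal totals, and 897 were higher and 799 lower after quantile normalization. Of the 24 genes named above, Fosb (adjusted p = 0.0563), Npas4 (0.0737), Rgs16 (0.0663) and Notch1 (0.0643) did not pass in the fit with the block. Without culture 3 of both groups, Gprc5a (0.0984), Fosb (0.181), Npas4 (0.0867), Nr4a2 (0.0665) and Txnip (0.0559) did not pass. Npas4 lost its call without DMSO 2 (0.0513), Notch1 without DMSO 1, DMSO 2 or cLTP 1 (0.0525 to 0.0569), Tsku and Zfp36l2 without DMSO 1, DMSO 2, cLTP 1 or cLTP 3 (0.0534 to 0.0907), and Rassf4 without DMSO 1, cLTP 1 or cLTP 3 (0.0515 to 0.0754).

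**Figure D1:**
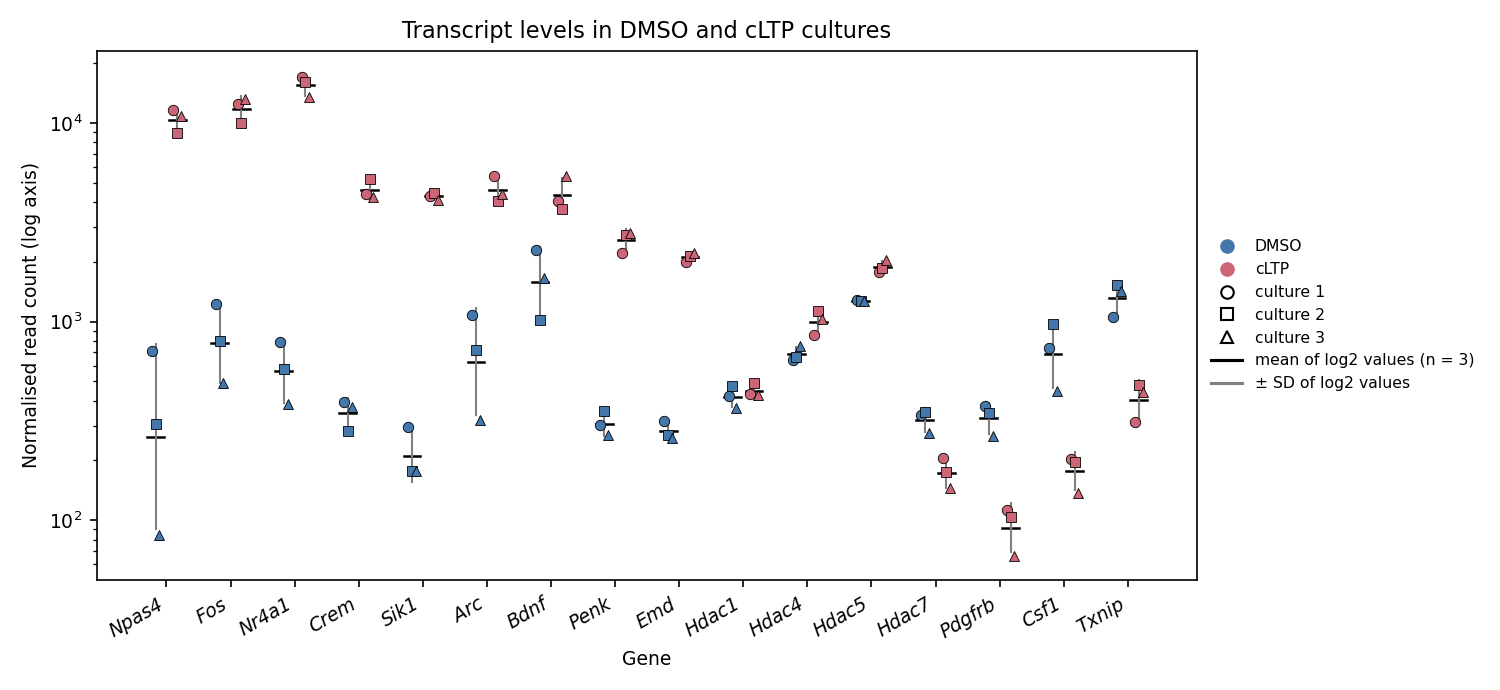
Normalised read counts (log axis) of 16 genes in each of the 3 DMSO (blue) and 3 cLTP (red) libraries, with the symbol giving the culture number, a black bar for the mean and a grey bar for the SD of the log2 values. The cLTP libraries lie above all DMSO libraries for the genes from Npas4 to Emd and for Hdac4 and Hdac5, below them for Hdac7, Pdgfrb, Csf1 and Txnip, and overlap with them for Hdac1.

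Immediate early transcription factors are among the genes that neurons switch on first after activity. Of 24 such genes 19 passed the test, each of them higher after cLTP, and 23 passed when adjusted over the list alone. The lowest p-values were those of Btg2, an antiproliferative cofactor, which rose from 476 ± 8.27 to 3780 ± 532, and Fosl2, an AP-1 subunit, which rose from 236 ± 34.1 to 1859 ± 92.3. The other members past the threshold were Crem, Per1, Junb, Nr4a1, Ier2, Maff, Nr4a3, Atf3, Jun, Nr4a2, Klf4, Fos, Egr1, Egr4, Srf, Fosb and Npas4. Fos itself went from 839 ± 372 to 11875 ± 1664 (15.1-fold), Junb from 939 ± 228 to 9571 ± 866 (10.4-fold) and Srf, the serum response factor, from 661 ± 90.3 to 1115 ± 92.9 (1.69-fold). The list was called by camera with a preset correlation (adjusted p = 1.8e-34) and not with an estimated one (adjusted p = 0.0964 with an estimated correlation). Without culture 3 of both groups, Egr4 did not pass (adjusted p = 0.126).

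Effector genes of neuronal activity, which encode signalling, scaffold and secreted proteins, rose in 26 of 28 cases, and 26 rose when adjusted over the list alone. Dusp1, a phosphatase that inactivates MAP kinases, went from 259 ± 34.8 to 3377 ± 243, and Tiparp, an ADP-ribosyltransferase, from 319 ± 51.7 to 3199 ± 114. The remaining members past the threshold were Gadd45g, Scg2, Pim1, Fbxo33, Plk2, Rgs2, Plk3, Dusp4, Syt4, Inhba, Gpr3, Trib1, Dusp5, Pcsk1, Dusp6, Ptgs2, Homer1, Gadd45b, Rgs4, Nptx2, Arc, Nrn1, Bdnf and Vgf. Arc, which acts in the removal of AMPA receptors from synapses, rose from 707 ± 382 to 4627 ± 725 (7.29-fold), and Bdnf, a neurotrophin, from 1665 ± 643 to 4398 ± 914 (2.75-fold). The camera call (adjusted p = 3.65e-33) did not hold with an estimated correlation (adjusted p = 0.0964 with an estimated correlation). With the culture number as a block, Arc (adjusted p = 0.069), Bdnf (0.113) and Nptx2 (0.0785) did not pass, and without culture 3 Bdnf (0.379), Nptx2 (0.309), Ptgs2 (0.262), Gadd45b (0.219) and Nrn1 (0.0549) did not. Vgf lost its call without DMSO 1, DMSO 2 or cLTP 2 (0.0579 to 0.0952) and after quantile normalization (0.0977).

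Targets of cyclic AMP and the transcription factor CREB showed the same direction: 24 of 27 passed the test, each higher after cLTP, and adjusted over the list alone 25 were higher and 1 lower. Many belong to the lists above as well. Sik1, given above, was also among them, and those not yet named were Penk, Pde4b, Stc1, Crh, Pde4d, Adcyap1, Gem, Sst and Areg. Crem, which encodes the cyclic AMP responsive modulator, rose 13.3-fold, from 349 ± 60.1 to 4640 ± 533. Pde4b and Pde4d, phosphodiesterases of the family that rolipram inhibits, rose 4.34-fold and 2.53-fold. The camera call (adjusted p = 1.8e-34) was lost with an estimated correlation (adjusted p = 0.0964 with an estimated correlation). Areg, at 5.08 ± 3.41 in DMSO cultures, lost its call without each library except DMSO 1 (limma adjusted p = 0.0601 to 0.155).

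Neuropeptides and secreted trophic factors rose in 12 of 24 cases, and in 16 when adjusted over the list alone. Penk, the precursor of enkephalins, rose from 308 ± 43.3 to 2581 ± 322 (8.36-fold), and Scg2, secretogranin, from 6335 ± 618 to 23576 ± 1394 (3.73-fold). The others past the threshold were Crh, Adcyap1, Inhba, Tac1, Fgf2, Sst, Nrn1, Chgb, Bdnf and Vgf. Crh, corticotropin-releasing hormone, rose 5.76-fold, Adcyap1, the precursor of the peptide PACAP, 4.01-fold, and Tac1, the precursor of substance P, 3.48-fold. Ntf3, a neurotrophin, was at 31.0 ± 12.6 and 19.6 ± 9.52 and did not pass (adjusted p = 0.387). The camera call (adjusted p = 2.27e-12) was lost with an estimated correlation (adjusted p = 0.0964 with an estimated correlation). Chgb lost its call without cLTP 1 (0.0742) and without culture 3 (0.0576).

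Hdac1 (ENSRNOG00000009568), the deacetylase named in the series, was at 422 ± 51.6 in DMSO cultures and 449 ± 35.5 in cLTP cultures. The log2 fold change was 0.10 with a 95% interval from -0.15 to 0.35 (limma adjusted p = 0.704), so a change of transcript level was not detectable. Hdac2, its closest relative, was at 905 ± 82.1 and 957 ± 75.5 (log2 fold change 0.08, 95% interval from -0.13 to 0.30, adjusted p = 0.706). Among 17 histone deacetylases and sirtuins, 3 members of class IIa changed: Hdac5 rose from 1276 ± 11 to 1895 ± 138 (1.48-fold) and Hdac4 from 687 ± 57.1 to 1006 ± 142 (1.46-fold), while Hdac7 fell from 322 ± 42.3 to 175 ± 29.8 (0.543-fold). The counts were the same when adjusted over the list alone, and with the block 3 were higher and 2 lower. Of 26 subunits of the Sin3, NuRD and CoREST complexes, which hold Hdac1, the 3 past the threshold fell: Sin3a (0.729-fold), Gatad2b (0.766-fold) and Rcor3 (0.722-fold); 1 higher and 3 lower passed when adjusted over the list alone, and 1 higher and 4 lower with the block. Camera called neither list (adjusted p = 0.921 and 0.767). With the block, Hdac4 (limma adjusted p = 1.21e-05), Sin3a (9.01e-05) and Gatad2b (0.000134) passed, as did Rcor3. The losses given next are from fits without the block. Hdac4 lost its call without DMSO 1, DMSO 2, cLTP 2 or cLTP 3 (0.0545 to 0.0865), Sin3a without DMSO 2 (0.0516), Gatad2b without DMSO 1, DMSO 2, cLTP 1 or cLTP 3 (0.0526 to 0.08) and Rcor3 without any 1 of the 6 libraries (0.0801 to 0.107) or culture 3 (0.116).

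Other chromatin genes moved in both directions. Emd, which encodes the inner nuclear membrane protein emerin, rose 7.51-fold, from 282 ± 31.0 to 2122 ± 106 (limma adjusted p = 1.3e-06). It and Hmgb2, a DNA-bending protein (84.1 ± 15.0 to 134 ± 15.9), were the 2 members past the threshold among 26 genes of the nuclear lamina, envelope and genome organisation, and 2 higher and 3 lower passed when adjusted over the list alone. Of 23 histone acetyltransferases and demethylases, Kdm6b rose 2.38-fold to 2123 ± 53.6, Kdm7a 1.80-fold and Kdm2a 1.34-fold, while Kdm4a and Kdm5b fell to 0.805-fold and 0.818-fold; adjusted over the list alone 4 were higher and 3 lower. Of 28 chromatin remodelling subunits, Chd7 rose from 483 ± 50.5 to 1184 ± 244, and Smarca5 (1.47-fold) and Chd1 (1.37-fold) rose too, while Arid1a fell from 2089 ± 94.0 to 1360 ± 50.1 and Chd8 from 1993 ± 85.0 to 1375 ± 136; the same numbers passed when adjusted over the list alone. Camera called none of these 3 lists (adjusted p = 0.904, 0.698 and 0.402), and with the block 5 higher and 5 lower, 6 higher and 8 lower, and 3 higher and 7 lower members passed. Kdm5b lost its call without any 1 library (0.0776 to 0.152), Kdm4a without each except cLTP 2 (0.0713 to 0.149), Hmgb2 without each except cLTP 3 (0.0551 to 0.137) and Chd1 without DMSO 1, DMSO 2, cLTP 1 or cLTP 2 (0.0537 to 0.1), and Kdm4a (0.0586) and Kdm5b (0.0523) also without culture 3.

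Few receptor, channel and synapse genes passed the test. Of 22 glutamate receptor genes, 0 passed in limma and in edgeR and 1 passed in DESeq2, 5 had an unadjusted p under 0.05 in limma, and 4 passed, all lower, when adjusted over the list alone. Grin2a, an NMDA receptor subunit, was at 888 ± 154 and 621 ± 95.6 (adjusted p = 0.0728; 9.66e-06 with the block, lower after cLTP). With the block, 1 glutamate receptor gene was higher and 7 were lower. Of 20 genes of the GABA system and 24 postsynaptic scaffold genes, 0 passed in limma, edgeR and DESeq2 (1 each at an unadjusted p under 0.05 in limma), and 0 in limma when adjusted over the list alone; with the block 4 were higher and 3 lower, and 1 higher and 4 lower. Of 22 presynaptic genes, Slc17a6, a vesicular glutamate transporter, rose from 289 ± 40.7 to 563 ± 142, and Bsn, a scaffold of the active zone, was at 6924 ± 915 and 5350 ± 519 (adjusted p = 0.0955, or 9.85e-06 with the block, lower after cLTP); 1 was higher when adjusted over the list alone, and 4 were higher and 1 lower with the block. Of 26 potassium and HCN channel genes, Kcnf1 rose 1.69-fold and Kcna2 fell from 3454 ± 384 to 2124 ± 201; these counts were the same when adjusted over the list alone, and with the block 1 was higher and 5 lower. With all 6 libraries, camera called none of these 5 lists without the block (adjusted p from 0.0951 to 0.971) and the channel list, downward, with it (adjusted p = 0.00865; adjusted p = 0.468 with an estimated correlation). Without the block, camera also called the channel list downward without DMSO 2 (0.00901), cLTP 3 (0.0029) or culture 3 of both groups (0.0234), the glutamate receptor list downward without cLTP 3 (0.0453), the scaffold list downward without DMSO 2 (0.0382) and the presynaptic list upward without DMSO 3 (0.0335) or cLTP 2 (0.0363). The channel, glutamate receptor, scaffold and presynaptic lists were higher in culture 3 of both groups, by median log2 differences of 0.18 to 0.35. Leaving out 1 library weights culture 3 unequally between the groups. The list calls made without 1 library can therefore reflect culture 3 as well as cLTP. Slc17a6 lost its call without DMSO 1, DMSO 2 or cLTP 1 (0.0533 to 0.0574).

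**Figure D2:**
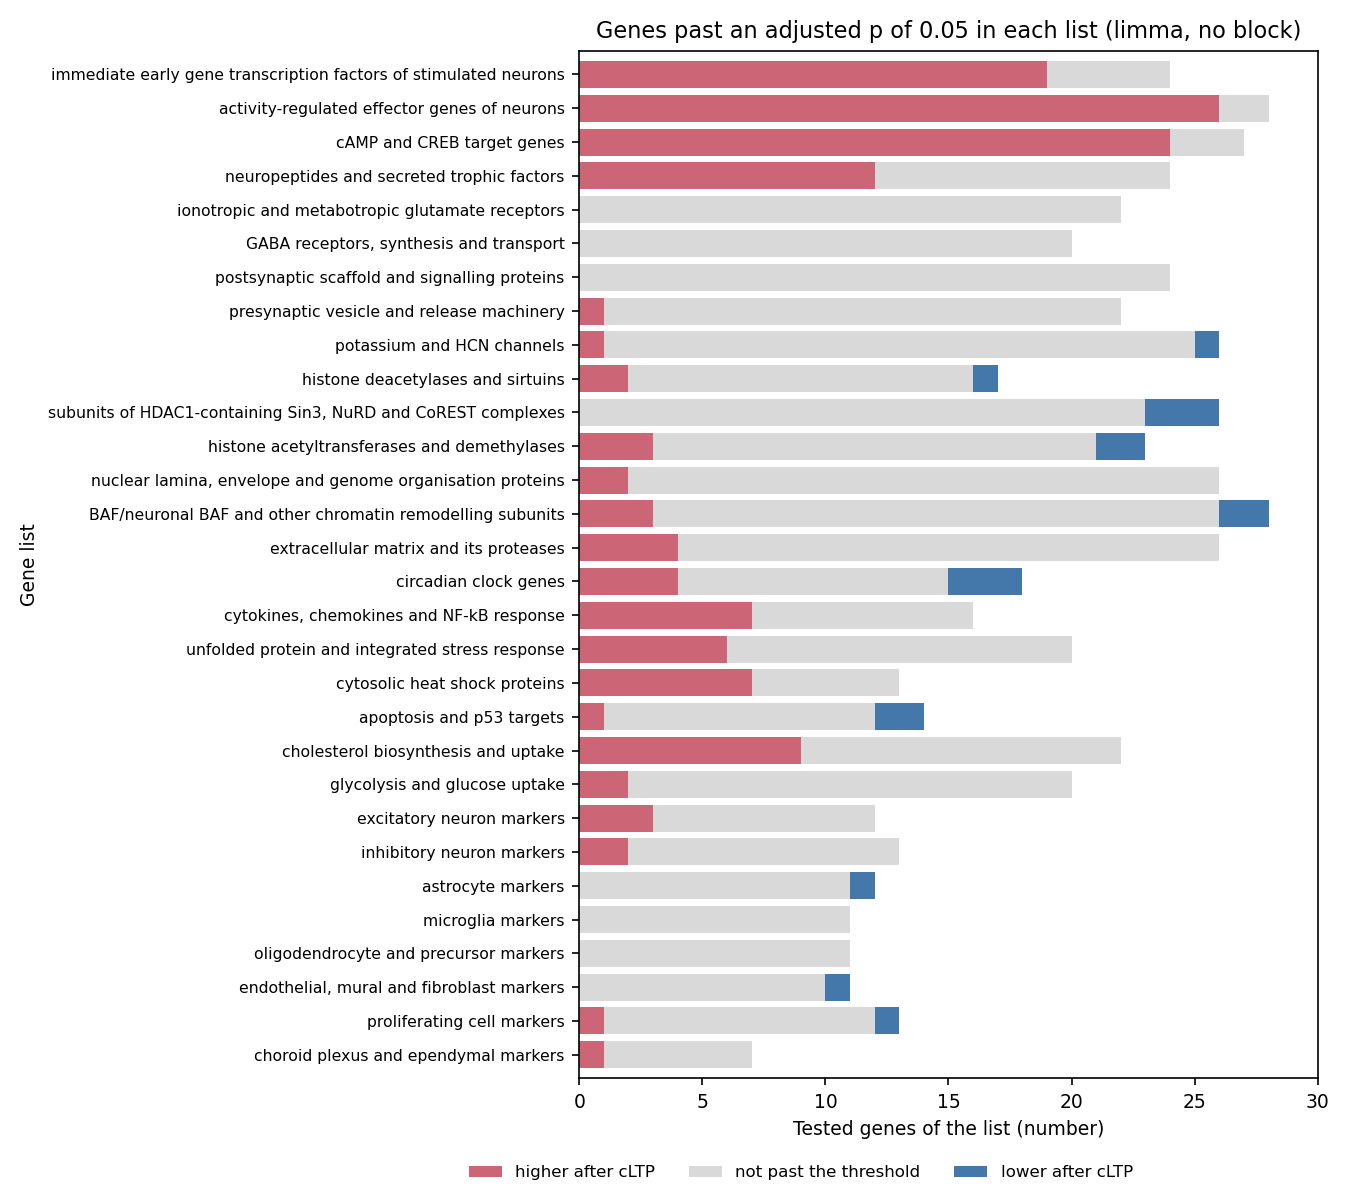
Number of tested genes of each of the 30 gene lists (horizontal axis) that were higher (red) or lower (blue) after cLTP past an adjusted p of 0.05 in limma without the block, or did not pass (grey). The lists of early genes, effector genes and CREB targets hold 19, 26 and 24 higher members, and the lists of glutamate receptors, GABA genes and postsynaptic scaffolds hold none past the threshold.

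Inflammatory and stress genes were higher in part. Of 16 cytokine, chemokine and NF-kB response genes, Nfkb1, Nfkbia, Il6, Cxcl1, Ccl2, Socs3 and Tnfaip3 passed, all higher, and 9 when adjusted over the list alone. Nfkb1 rose from 425 ± 32.0 to 1720 ± 319, its inhibitor Nfkbia from 288 ± 36.8 to 804 ± 85.9, and Il6 from 3.08 ± 1.92 to 72.8 ± 7.5. Il1b was at 1.30 ± 1.51 and 1.36 ± 2.35 and did not pass (adjusted p = 0.934). Microglia, a source of such cytokines, were represented by markers mainly in culture 3 of both groups. Without culture 3 of both groups, camera at the preset correlation still called this list upward (adjusted p = 3.72e-08). Of 13 cytosolic heat shock genes, Dnajb1, Hsph1, Hspa1a, Hspa4, Hspa8, Hspe1 and Bag3 rose, 10 when adjusted over the list alone and 12 with the block; Dnajb1 rose from 568 ± 26.8 to 1153 ± 164 and Hsph1 from 2601 ± 235 to 4853 ± 566. Of 20 genes of the unfolded protein and integrated stress response, Ppp1r15a (2.24-fold), Chac1 (1.59-fold), Atf4, Hspa5, Dnajb9 and Xbp1 rose, 9 when adjusted over the list alone and 16 with the block, while Trib3 was at 396 ± 125 and 397 ± 134. Camera called these 3 lists (adjusted p = 7.44e-07, 5.12e-08 and 6.18e-06), and none with an estimated correlation (adjusted p = 0.0964, 0.156 and 0.516 with an estimated correlation).

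Socs3 lost its call without DMSO 1, cLTP 1 or cLTP 2 (limma adjusted p = 0.0535 to 0.0864), Tnfaip3 without DMSO 2, cLTP 1 or cLTP 2 (0.0894 to 0.0999) and Ccl2 without culture 3 (0.0688). Hspa8 lost its call without DMSO 1, DMSO 2 or cLTP 1 (0.0578 to 0.0684), Hspe1 without these or cLTP 2 (0.0538 to 0.0679) and Bag3 without DMSO 2, cLTP 1 or cLTP 2 (0.0673 to 0.121). Atf4 lost its call without DMSO 1 (0.0543), Hspa5 without DMSO 1 (0.0947) or cLTP 2 (0.0533), Dnajb9 without DMSO 1, cLTP 1 or cLTP 2 (0.0711 to 0.0833) and Xbp1 without any 1 library (0.0685 to 0.17). With equal totals Hspa8 (0.0609), Hspe1 (0.0564) and Xbp1 (0.265) were higher but did not pass, and after quantile normalization Hspa8 (0.171), Atf4 (0.0835), Dnajb9 (0.0511) and Xbp1 (0.162) were higher but did not. Xbp1 also did not pass with TMM scaling (0.0524).

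Of 22 cholesterol synthesis and uptake genes 9 passed, all higher; adjusted over the list alone 11 were higher and 1 lower, and with the block 13 were higher and 2 lower. Mvk, mevalonate kinase, rose from 147 ± 9.29 to 318 ± 51.6 (2.14-fold). Idi1, Sqle, Nsdhl, Fdps, Insig1, Sc5d and Pmvk also rose, while Dhcr7 was at 566 ± 87.0 and 433 ± 57.4 (adjusted p = 0.124; 0.000303 with the block). Of 20 glycolysis and glucose uptake genes, the neuronal glucose transporter gene Slc2a3 (2.69-fold) and the hexokinase gene Hk2 (1.69-fold) rose, 2 also when adjusted over the list alone and 12 with the block. Camera called both lists (adjusted p = 0.000186 and 0.000317), and neither with an estimated correlation (adjusted p = 0.465 and 0.467 with an estimated correlation). Leaving out 1 library ended the calls of Sqle (DMSO 1, 0.0505), Nsdhl (DMSO 2 or cLTP 1, 0.0662 and 0.066), Insig1 (cLTP 1 or cLTP 2, 0.0738 and 0.0711), Sc5d (DMSO 2, cLTP 1 or cLTP 3, 0.0669 to 0.0944), Fdps and Pmvk (DMSO 1, DMSO 2, cLTP 1 or cLTP 3, 0.0577 to 0.116) and Hk2 (DMSO 1 or any cLTP library, 0.0606 to 0.132). Fdps, Sc5d and Pmvk were higher but did not pass with equal totals (0.0663 to 0.135), nor did Fdps (0.121) and Sc5d (0.0757) after quantile normalization.

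Clock genes, matrix genes and apoptosis genes each held members in both directions or a few large increases. Per1, a period gene and CREB target, rose 5.36-fold, from 1065 ± 126 to 5693 ± 396, Cry2 rose 3.65-fold, and Ciart and Nr1d1 rose 2.57-fold and 1.47-fold, while Dbp (0.666-fold), Per3 (0.667-fold) and Arntl (0.685-fold) fell. Of the 18 clock genes 7 were higher and 7 lower when adjusted over the list alone, 7 higher and 8 lower with the block, and the list's median log2 fold change was -0.18 although camera gave the direction as up (adjusted p = 0.904). Of 26 extracellular matrix and protease genes, Adamts1, Plat, Has2 and Adamts9 rose, 6 when adjusted over the list alone, and 11 were higher and 1 lower with the block; Plat, tissue plasminogen activator, went from 965 ± 146 to 3393 ± 578. Camera called the matrix list (adjusted p = 0.00251), but not with an estimated correlation (adjusted p = 0.516 with an estimated correlation). Of 14 apoptosis and p53 target genes, Pmaip1 rose from 183 ± 15.2 to 274 ± 20.4, Tp53inp1 fell to 0.490-fold and Sesn1 to 0.687-fold, with 2 higher and 3 lower when adjusted over the list alone and 3 in each direction with the block (camera adjusted p = 0.904). Arntl lost its call without each library except DMSO 3 (0.0669 to 0.104), Per3 without DMSO 1 (0.0574), and Sesn1 without each library except cLTP 1 (0.0655 to 0.125) or without culture 3 (0.101).

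Few markers of the cell types found in such cultures passed the test. Of 12 astrocyte markers the transcription factor Sox9 fell, from 1622 ± 375 to 965 ± 76.7, 1 passed when adjusted over the list alone, and 3 were higher and 1 lower with the block; Sox9 did not pass with the block (adjusted p = 0.125) or without any 1 library except DMSO 3 (0.0626 to 0.112). Of 11 vascular markers Pdgfrb fell, as given above, also when adjusted over the list alone. Of 12 excitatory neuron markers, Fezf2 (2.84-fold), Bhlhe22 (2.14-fold) and Slc17a6 (1.92-fold) rose, 3 were higher and 1 lower when adjusted over the list alone, and 4 higher and 1 lower with the block. Camera did not call the excitatory list (adjusted p = 0.118) but did with the block (adjusted p = 0.0419, and adjusted p = 0.785 with an estimated correlation). Without the block it did so upward without DMSO 3 (0.00243), cLTP 2 (0.00868) or culture 3 of both groups (0.00458). Excitatory markers were higher in culture 3, by median log2 differences of 0.30 in DMSO and 0.23 in cLTP libraries. The calls without DMSO 3 or cLTP 2 can therefore reflect culture 3 as well as cLTP. Of 13 inhibitory neuron markers Dlx2 (2.02-fold) and the peptide gene Sst (1.37-fold) rose, 3 when adjusted over the list alone and 9 with the block; camera called this list upward (adjusted p = 0.00251), but not with an estimated correlation (adjusted p = 0.545 with an estimated correlation). Of 13 proliferation markers Pcna rose 1.97-fold and Plk1 fell from 34.3 ± 0.128 to 18.0 ± 3.76, and of 7 choroid plexus markers Aqp1 rose from 2.49 ± 0.460 to 8.83 ± 1.63; the same genes passed when adjusted over the list alone. Plk1 lost its call without each library except cLTP 2 (0.0843 to 0.122) and Aqp1 without any 1 library (0.0633 to 0.124), and both without culture 3 (0.121 and 0.0809). Of 11 oligodendrocyte and 11 microglia markers 0 passed in limma, edgeR (8 and 1 tested) or DESeq2 (8 and 7 tested), or in limma when adjusted over the list alone, with 1 and 0 at an unadjusted p under 0.05 in limma; 1 oligodendrocyte marker was higher with the block. With all 6 libraries, camera called none of the astrocyte, vascular, proliferation, choroid plexus, oligodendrocyte and microglia lists (adjusted p from 0.698 to 0.904). Without cLTP 3 it called the microglia list downward (adjusted p = 0.0462). That fit keeps DMSO 3, where microglia markers were higher than in DMSO 1 and 2 by a median log2 difference of 5.11. The call therefore cannot be read as an effect of cLTP.

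The libraries of culture 3 differed from the others in cell type markers in both groups. The 11 microglia markers had 1072 reads in DMSO culture 3 and 1057 in cLTP culture 3, against 42 to 55 in each of the other 4 libraries. Astrocyte markers were lower in culture 3 than in cultures 1 and 2 by a median log2 difference of -0.57 in DMSO and -0.36 in cLTP libraries, and excitatory neuron markers were higher by 0.30 and 0.23. Without culture 3 of both groups, 1094 genes were higher and 627 lower after cLTP in limma.

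**Figure D3:**
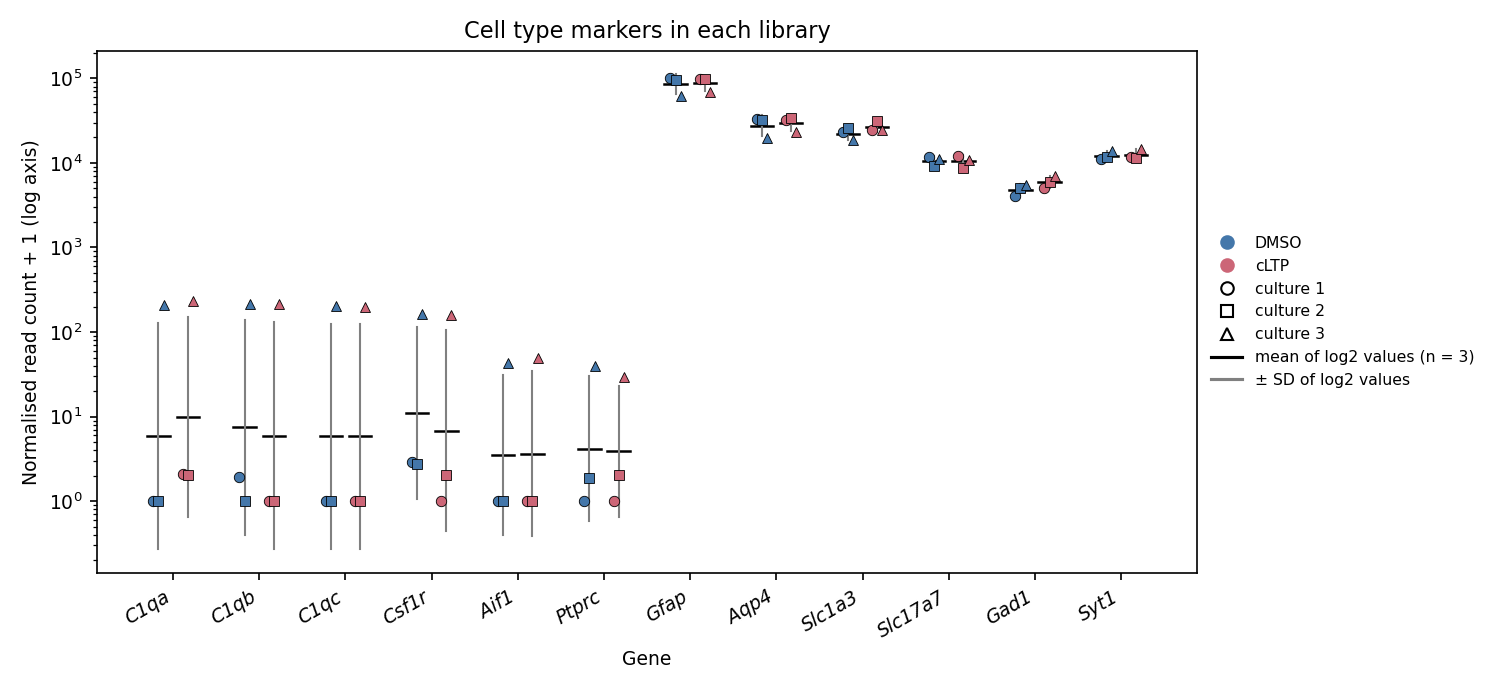
Normalised read counts + 1 (log axis) of 12 cell type markers in each library, with DMSO in blue, cLTP in red, the symbol giving the culture number, a black bar for the mean and a grey bar for the SD of the log2 values (n = 3). The complement genes C1qa, C1qb and C1qc reach 197 to 231 (before adding 1) in culture 3 of both groups and lie near 0 in the other libraries, while Gfap, an astrocyte marker, lies between 62521 and 101520 in all of them.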

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

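The edgeR tests with TMM (without and with the block), TMM scaling, equal totals of the deposited values and the fits without culture 3 were chosen after the data were seen. The other edgeR settings were planned. Against 1561 genes in limma, pseudocounts of 0.5 and 5, no filter, a mean of at least 10, TMM scaling, DESeq2, limma-voom and edgeR without the block, with TMM or RLE factors, gave totals between 1527 and 1642, of which 1460 to 1550 were among the 1561, and edgeR at a mean count of at least 50 gave 1527 (1378). Quantile normalization gave 1696 (1434 of the 1561), leaving out culture 3 of both groups 1721 (1343) and doing so with the block 2138 (1410). With the replicate block 4075 genes passed (2225 higher, 1850 lower), with 1544 of the 1561 among them, and edgeR with the block gave 4124 (2168 higher, 1956 lower). The 2531 genes gained with the block had a median absolute log2 fold change of 0.28. A test against a fold of 1.2 left 656 (564 higher, 92 lower), a change of at least 2-fold 542 (470 higher, 72 lower) and an adjusted p of 0.01 left 784 (618 higher, 166 lower), each by construction. Equal totals shifted the median of all genes by -0.11 and gave 1322 lower and 823 higher genes, against 573 and 988, and in edgeR 1458 of 2272 genes were lower on total counts, against 648 of 1623 with TMM. Leaving out 1 library gave totals from 953 to 1408 and lower genes from 227 to 469: without DMSO 1 953 passed (227 lower), without DMSO 2 971 (231), without cLTP 1 954 (250), without cLTP 2 1150 (382) and without cLTP 3 1213 (347). These fits held fewer libraries. The fit without culture 3 of both groups held fewer still and called 1721, so the number of libraries alone does not account for the drop. Leaving out 1 library also weights culture 3 unequally between the groups. Other causes were not tested. The 11 list calls fell to 0 with an estimated correlation. Of 208 genes named or listed, 147 passed the main test, and 0 of these changed direction in any of 25 settings; 108 passed whichever library was left out, edgeR without a filter lost 14, 8 were lost and 26 gained with the block, and the block changed no list call other than those given with the channel and excitatory neuron lists. Genes near 3 reads per library, such as Aqp1 and Areg, are limited by depth.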

Other observations

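The summaries of ribosomal and control values and the test of a lower astrocyte share were chosen only after the results were seen. Of 76 cytosolic ribosomal protein genes with a mean value of at least 10, 3 passed in limma and 61 with the culture number as a block, all of them higher, against 988 and 2225 higher among all 17315 genes tested. No set test was run on them. Their median log2 fold change was 0.22. With equal totals the median was 0.11 and 1 passed, and without culture 3 of both groups 18 passed with the block. Without the block, 0 passed without cLTP 1, 1 without DMSO 1 or cLTP 3 and 2 without DMSO 2, DMSO 3 or cLTP 2, and 8 passed in DESeq2.

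The spread between cultures was compared for 45 early and effector genes past the threshold. The median SD of log2 values was 0.325 among DMSO and 0.176 among cLTP libraries, against 0.104 and 0.111 for 7585 other genes, and it was larger in DMSO for 38 of the 45. DMSO 1 held the highest of the 3 control values for 34 of the 45 genes. Npas4, for example, was at 709, 306 and 84.7 in DMSO 1, 2 and 3. The 45 genes were all higher after cLTP, so their control values were the lower ones, and low counts spread more on the log2 scale. How much of the difference in SD this gives was not tested. Genes of these lists were also correlated, so the 45 are not independent observations.

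Libraries were also split in every other way into 3 and 3. The real split gave 1561 genes in limma and the highest of the 9 others gave 0. At an unadjusted p under 0.05 in limma, the real split gave 3644 genes and the others up to 1801. Only 1 of the 10 splits, the real one, gave as many as 1561, and 10 splits are too few for a share under 0.05. Each other split mixes cLTP and DMSO libraries on both sides, so the treatment difference widens the spread within them. Few or no calls were therefore likely from the start, and the 0 does not measure chance. The 3 other splits that part all same-numbered pairs also gave 0 genes. For the gene lists, 6 of the 10 splits gave at least the real number of 11 camera calls. The highest other split gave 14 and the highest that parts all pairs gave 11. Here too the splits are too few for a share under 0.05. The other splits also keep part of the treatment difference between their sides, and some part culture 3 from the rest. Their list calls therefore do not measure how often chance would give 11.

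Microglia transcripts were found almost only in culture 3 of both groups. C1qa was at 0, 0 and 208 in DMSO 1, 2 and 3 and at 1.13, 1.04 and 231 in cLTP 1, 2 and 3, and Csf1r at 163 and 157 in the culture 3 libraries and at most 1.90 in the others. A second list of 40 microglia genes, written before its values were seen, was also higher in culture 3. The median log2 difference was 2.57 in DMSO and 2.79 in cLTP libraries, with 38 of 39 tested genes higher in each. RNA of microglia in these libraries would give this. The 2 lists were not chosen to tell microglia from other macrophages, so RNA of other macrophages stays open too. Of the 39 genes, 0 are in another list and 9 had a mean of at least 10 in the libraries of cultures 1 and 2. A lower astrocyte share alone would raise all other cell types alike, but the microglia markers exceeded the highest of 4 other marker lists by 4.68 or more (log2). Carry-over of RNA or reads into both libraries stays open, as the markers differed by a median of only -0.03 between them, and so does a difference between the preparations, which the labels do not describe.

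Genes named Zfp followed by a number, mostly zinc finger proteins, were lower after cLTP more often than others. Of 244 tested, 56 were lower and 12 higher in limma, and 23.0% were lower against 3.03% of the 17071 other genes. Low read counts do not account for this: the share exceeded the highest of 10000 sets matched on expression (10.2%) by 12.7 percentage points, and with gene span matched too the excess was 10.97 points. Their median differed from that of matched genes by -0.26 (95% interval -0.31 to -0.22), so the scaling of libraries would not account for it, but it moved the number called. Among 232 with a mean of at least 10, 55 were lower, against 97 with equal totals, 103 in edgeR on total counts, 107 with the block and 26, 24, 26 and 29 without DMSO 1, DMSO 2, cLTP 1 and cLTP 3. With 1 library left out, the median log2 fold change of the 232 lay between -0.29 and -0.23. The matched sets were drawn over genes and not over cultures, so neither their shares nor the 95% interval above measures the spread between cultures. Reads shared between paralogs were not tested, nor was any biological explanation.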
